A study of Mus musculus with 5 samples.

How the data were processed

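RNA from 5 sorted mouse thymocyte populations was extracted with StrataPrep kits, made into biotin-labelled cRNA and hybridised to Affymetrix arrays, per the labels' protocols. Each population had 1 array. The deposited values are probe set signal intensities on a linear scale. They were made by the authors with Affymetrix Expression Console 1.0 and MAS5, per the submitters' processing notes. The settings of the algorithm, the scanner and the detection calls are not given in the sources used here. The mean signal after trimming 2% at each end was between 500.3 and 500.4 on every array, as global scaling to 1 target would give. Such scaling assumes equal total signal, so a difference in total mRNA per cell cannot be seen. The largest signal on an array was between 41421 and 58637.

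The table held 12488 probe sets, of which 66 were controls. By the platform's annotation, 10855 probe sets had 1 gene symbol, 396 several and 1237 none. Symbols were updated through gene identifiers with the RefSeq gene table of GRCm38.p6 for 10839 probe sets, which altered 22 symbols, and 16 were kept as given. Probe sets with several symbols or none, and controls, were left out, which left 8251 genes. No genome build goes with the array values, so no coordinates are given.

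Values were used as deposited. The floor was the median (50th percentile) of all gene probe set values, 130.4. Values under it were set to it before taking log2. The 19 control probe sets for transcripts of other organisms that were not spiked stayed at or below 67.6 on every array. For the 2073 genes with more than 1 probe set, the one with the highest mean floored log2 signal was used. Where probe sets of a gene disagree, this choice sets the value.

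With 1 array per population no test was possible, and no p-value was computed. Genes at least 2-fold higher or lower were counted for the 4 consecutive comparisons and for DP against DN1. The peak population was counted over genes at least 2-fold apart between the highest and lowest array. Error was described by the SD of the difference in log2 ratio between the 2 brightest probe sets of a gene, both above the floor on both arrays, and by the 9 spiked controls. Pearson correlations across genes between neighbouring arrays were 0.90, 0.97, 0.98 and 0.92 in stage order, and genes are not independent replicates.

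For 29 gene lists the median log2 ratio of members above the floor on either array was set against 10000 random lists of the same size, matched on mean log2 signal in 10 bins. The percentile describes these arrays and tests no population. Over the 137 list and comparison pairs with at least 3 measured members, 29 were at or above percentile 99 and 41 at or below percentile 1. Lists of genes drawn at random would fall there in about 2% of cases. Random lists ignore correlation between listed genes, some lists share members, and DP against DN1 repeats the consecutive comparisons. The 2% is therefore no expected count for these pairs. The lists, the floor, the 2-fold size, the rule for named genes and most alternatives were fixed before the data were examined. The percentiles of 1 and 99 were not among those choices.

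The named genes are, for each consecutive comparison, the 10 highest and 10 lowest ratios among genes measured on both arrays, and the 5 brightest genes in each direction whose other value was at or under the floor. To these come list members at least 2-fold apart with the largest difference, up to 4 per list and up to 6 for Notch lists. Notch1, Notch3 and the sort markers are always given. DP against DN1 uses list members and sort markers alone. Values of other list members, where printed, were chosen after they were seen.

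The counting step was tested on simulated arrays, with the spread between probe sets as noise, on 8251 genes of which 200 were given known folds. Those 200 were drawn only from genes with a mean signal well above the floor, so recovery near the floor was not measured. The noise held no error shared by an array and no variation between sorts or mice, so the rates below leave these out. It was drawn from a normal distribution with the same SD at every signal level. The rates among unchanged genes follow largely from that SD and are no error rates of the real calls. For a 3-fold change it recovered 95 of 100 genes in DN2 against DN1, 93 in DN3 against DN2, 98 in preDP against DN3, 94 in DP against preDP and 92 in DP against DN1. For a 6-fold change it recovered 99, 100, 99, 100 and 100. Among unchanged genes above the floor it called 0.44%, 0.22%, 0.05%, 1.32% and 1.69%. The list step was run on 4825 genes of preDP against DN3, with lists of 20 genes drawn at random. It called 3 of 200 unshifted lists and 199 of 200 lists shifted by 0.5.

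Alternatives were quantile normalisation, scaling to an equal median, floors at the 35th and 65th percentile and a constant added in place of a floor. Others were the mean over probe sets, leaving out shared probe sets (371 with the suffix _s_at and 0 with _x_at) and a 3-fold size. Probe sets with the suffix _f_at, which can read a gene family, were not among the shared ones left out. The setting of plain probe sets alone left them out, with those of suffix _r_at, _i_at and _g_at. Named genes read by an _f_at probe set include H2-K1, H2-D1, H2-Q1, Trav9d-3, Igkv6-23 and Eif2s3y. Plain probe sets alone, counts without genes of other cell types or of the cell cycle and ribosome lists, and leaving out the DN1 or DP array were added after seeing the data. The tolerance for list medians in those comparisons was first 1 SD of random list medians and was widened to 1.96 SDs after the first run. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.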

Results

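Gene expression was measured in 5 populations of thymocytes sorted from male C57BL6 mice of 5 weeks, for which thymuses of 10 mice were used. Whether RNA of the mice was pooled is not stated. Developing T cells pass through double negative (DN) stages, which lack CD4 and CD8, before they become double positive (DP) for both coreceptors. The DN1, DN2, DN3 and pre-double positive (preDP) populations were lineage negative and CD24 positive, and were separated by CD44 and CD25. DN1 was CD44 high and CD25 negative, DN2 CD44 high and CD25 positive, DN3 CD44 low and CD25 positive, and preDP CD44 low and CD25 negative. These 4 populations came from blast enriched thymocytes, whereas DP cells were sorted as CD4 and CD8 positive from total thymocytes. Stage and cell source therefore cannot be separated for DP.

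Each population was represented by 1 Affymetrix array, so there were no replicates. No p-value or standard error could be had, and the number of arrays limits the precision. Genes were counted by size, as at least 2-fold higher or lower, and every fold below compares 2 arrays. Of 8251 genes, 5443 were above the floor (a signal of 130.4) on at least 1 array and 4000 on all arrays. The number above it declined from 4935 genes in DN1 to 4684 in DN2, 4621 in DN3, 4582 in preDP and 4522 in DP. A fold against a value at or under the floor is given as at least that size.

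One internal measure of error came from genes read by more than 1 probe set. The log2 ratios of a gene's brightest and second probe sets differed with an SD of 0.53 for DN2 against DN1, 0.44 for DN3 against DN2, 0.43 for preDP against DN3 and 0.59 for DP against preDP. These rest on 573, 597, 603 and 566 genes. Among genes at least 2-fold apart by the brightest probe set, the second pointed the same way for 56 of 58, 19 of 21, 16 of 18 and 111 of 118 genes in the same order. It was itself at least 2-fold apart for 27, 10, 5 and 74 of them. The spread covers disagreement between probe sets on the same 2 arrays. Error shared by an array, such as that of RNA preparation or labelling, and variation between sorts or mice are left out. The 9 spiked hybridisation controls had mean log2 ratios of -0.18, 0.23, -0.39 and 0.20 in the 4 consecutive comparisons. Ratios of 3' to 5' signal, a sign of RNA quality, were 3.06, 3.08, 3.31, 2.79 and 2.83 for actin and 2.04, 1.70, 1.76, 1.39 and 1.92 for Gapdh from DN1 to DP.

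Genes of the sort markers were read first, as a check on the labels. Il2ra, which encodes CD25, had signals of 1156 in DN2 and 439 in DN3, the populations gated as CD25 positive, and was under the floor on the other 3 arrays. Cd4 reached 5096 in DP. It was 132 in DN3, just above the floor, and under it elsewhere. Cd8a was 20020 in DP, 2031 in preDP and 755 in DN1, and under the floor in DN2 and DN3. Cd24a was between 6849 and 14356 on all arrays. All 3 probe sets of Cd44 were under the floor on every array, so this gene checks nothing.

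The series' title concerns separate functions of Notch1 and Notch3, receptors of the Notch family, in steady-state thymic lymphopoiesis. Their profiles differed in shape. Notch1 had a signal of 3032 in DN1, 7325 in DN2 and 6926 in DN3, then 2535 in preDP and 1358 in DP. It was 2.42-fold higher in DN2 than in DN1, 1.06-fold apart between DN2 and DN3, 2.73-fold lower in preDP than in DN3 and 1.87-fold lower in DP than in preDP. The second Notch1 probe set, of lower signal, gave 243, 514, 656, 293 and 63.6 over the same arrays. Notch3 was close to the floor in DN1, at 158, and stood at 682 in DN2 and 2152 in DN3. It was 4.33-fold higher in DN2 than in DN1 and 3.16-fold higher in DN3 than in DN2. In preDP it was 4.35-fold lower than in DN3, at 495, and in DP it was 270. Notch3 was thus highest in DN3, whereas Notch1 was nearly level over DN2 and DN3. With the floor at the 65th percentile of values, the log2 ratio of Notch3 in DN2 against DN1 was 1.01 in place of 2.11. The signals of the 2 genes come from different probe sets and were not set against each other. Notch2 was 436 in DN1 and 180 in DN2 and under the floor from DN3 on. Notch4 was 354 in DN1 and under the floor elsewhere. DN1 also held high signal of myeloid, dendritic and B-cell genes, given below. Every fold against DN1 may therefore reflect the makeup of the sorted cells as well as the stage.

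Known Notch target genes of T-lineage cells were highest around DN3. Hes1, a transcriptional repressor, had signals of 706, 1119, 1853, 232 and 110 from DN1 to DP. Dtx1, a regulator of Notch signalling, was 1487 in DN3 and at most 227 on the other arrays. Ptcra, the invariant chain of the pre-T-cell receptor, was under the floor in DN1 and DN2, 3692 in DN3, 1181 in preDP and 945 in DP. Myc peaked later, at 1347 in preDP, and was under the floor in DP. Of the 6 listed targets measured in DN2 or DN3, 3 were at least 2-fold higher in DN3 and 1, Il2ra, was lower. The list's median log2 ratio was 1.21, above every one of 10000 random lists matched on signal. It was 0.77 without Notch3, without Dtx1 or without Ptcra, and 1.66 without Hes1, without Il2ra or without Myc. With the floor at the 35th percentile it was 0.75. In preDP against DN3 the median was -1.94, below every random list, with 5 of 6 members lower. The list holds Notch3 itself and the gate gene Il2ra. Listed Notch pathway modifiers, such as processing enzymes and glycosyltransferases, had medians of -0.16, -0.13, 0.10 and 0.47 over the consecutive comparisons, at percentiles between 9.88 and 93.0 of random lists. Among them Itch was 2.35-fold and the glycosyltransferase gene Rfng 2.21-fold higher in DP than in preDP. Numb was 2.37-fold higher in DN3 than in DN2, but under the floor in both with plain probe sets alone. The receptor and ligand list had medians of -0.00 in DN2 against DN1 and -0.08 in DN3 against DN2, at percentiles 46.1 and 36.3.

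**Figure D1:**
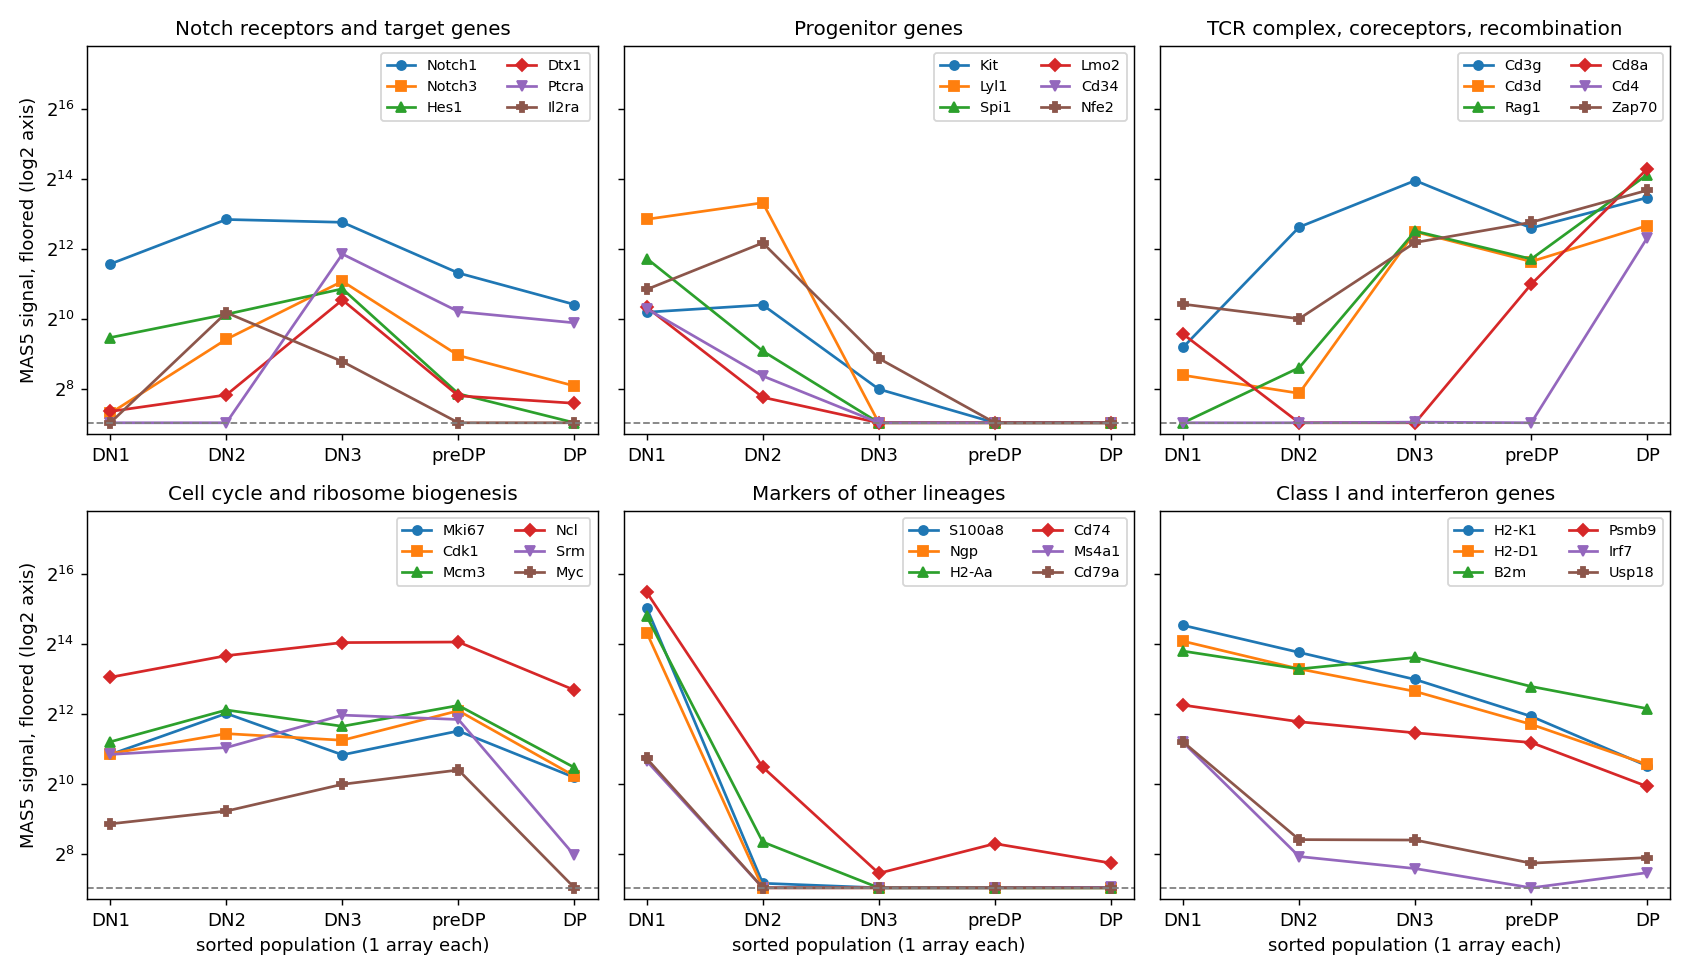
Signal of 36 genes (log2 axis, values under the floor drawn at the dashed line) over the 5 sorted populations, 1 array each; the genes are list members picked for the plot after their values were seen. Notch3, Dtx1 and Ptcra peak in DN3, at 2152, 1487 and 3692, while S100a8 and H2-Aa are high in DN1 alone.

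The comparison of DN2 with DN1 asks what distinguishes the first CD25 positive stage. DN2 had higher levels of Trgv4, Cd3g, Thy1, Il7r and proliferation genes, and DN1 had far higher levels of myeloid, dendritic and B-cell genes. Trgv4 and Trgv1, variable segments of the T-cell receptor gamma locus, were 13.3-fold and 6.09-fold higher in DN2. Cd3g, a chain of the CD3 complex, was 10.8-fold higher, Thy1 6.57-fold and the interleukin 7 receptor gene Il7r 5.06-fold. Il2ra was at least 8.87-fold higher. Myl10, Akr1c13, Rgcc, Fgf3 and Scin were also among the 10 genes with the highest ratios of those above the floor on both arrays, at 13.2-fold, 11.6-fold, 4.95-fold, 4.95-fold and 4.85-fold. In all, 245 genes were at least 2-fold higher in DN2 and 441 lower, of 5154 above the floor on either array.

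Among the genes lower in DN2, 14 of 16 measured myeloid markers were at least 2-fold lower, and the list's median log2 ratio was -4.08. S100a8, S100a9, Camp and Ngp, products of neutrophils, had signals of 33502, 18554, 22708 and 20481 in DN1. S100a8 was 235-fold lower in DN2 and Camp 171-fold, while Ngp was at least 157-fold and S100a9 at least 142-fold lower. Of 12 dendritic cell markers, 11 were lower, with a median of -3.81. The class II genes H2-Aa, H2-Eb1 and H2-Ab1 were 87.6-fold, 80.6-fold and 60.6-fold lower. B-lineage markers were lower for 9 of 13 members, with a median of -1.74. Ighm was 17.6-fold lower and Ms4a1 at least 12.3-fold. Igha was 144-fold lower and the kappa variable gene Igkv6-23 was 70.4-fold lower. All 3 medians were below every random list. With the mean over probe sets the myeloid median was -2.73 and the B-lineage median -1.01. The median of natural killer and innate lymphoid markers was -0.95, at percentile 0.29, with 3 of 7 lower. Erythroid markers had a median of 0.33, with 1 of 4 higher and 1 lower, and stromal markers one of -0.89, with 2 of 4 lower. Without 112 genes of other cell types, immunoglobulins and class II, a choice made after seeing the values, 244 genes were higher and 380 lower.

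Proliferation genes were higher in DN2. For S phase genes 10 of 24 were at least 2-fold higher and none lower, with a median of 0.93, and Rrm1, a subunit of ribonucleotide reductase, was 2.54-fold higher. For genes of G2 and mitosis 10 of 23 were higher and none lower, with a median of 0.95, and Mki67 was 2.26-fold higher. Both medians were above every random list. T-lineage transcription factors had a median of 0.68 at percentile 99.8 (1.09 with the higher floor), with 5 of 13 higher and 2 lower. Gata3 was 3.21-fold and Gfi1 3.39-fold higher, whereas Spib was at least 7.90-fold lower. Recombination genes had a median of 0.98, with Rag1 at least 2.98-fold higher. The list of ribosome biogenesis genes and Myc targets had a median of 0.56 at percentile 99.7, with no member 2-fold apart. Several groups were lower in DN2 alongside the markers of other cell types. Chemokine receptor and homing genes had a median of -1.25 (-0.53 with the higher floor), cytokine receptors -0.59, class I and interferon genes -0.77 (-0.48 with the higher floor), and mature single-positive markers -1.85. Immediate early and dissociation stress genes had one of -0.70, with 5 of 19 lower. Irf7 was 9.59-fold lower, Ccr2 at least 10.9-fold and Csf1r at least 12.0-fold. Among progenitor genes, 5 of 14 were lower and 1 higher, at a median of -0.52 and percentile 1.10. Spi1 and Cebpa, regulators of myeloid cells, were 6.26-fold and 6.52-fold lower, while Nfe2 was at 4606 in DN2 and 1832 in DN1. The cyclin D1 gene Ccnd1 was above the floor in DN1 alone of the 2 arrays.

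The median log2 ratio of all genes measured on both arrays was 0.18 in this comparison and under 0.03 in the other consecutive ones. Random lists carry this shift, so the percentiles are relative to it. With arrays scaled to an equal median, 144 genes were higher and 519 lower, or 21.7% higher in place of 35.7%, and the all-gene median was 0.03. The T-cell receptor complex list, with 2 of 13 higher and 1 lower, had a median of -0.24 at percentile 0.71, but 0.01 under quantile normalisation and 0.45 with the higher floor, so it has no settled direction. The median of the glycolysis list was -0.19, at percentile 0.53.

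**Figure D2:**
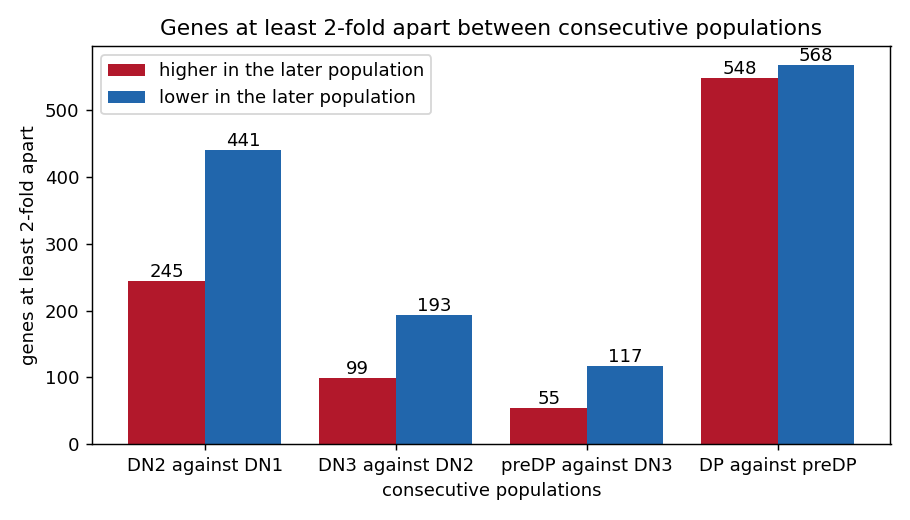
Number of genes at least 2-fold higher (red) or lower (blue) in the later of 2 consecutive populations, 1 array each. The counts are 245 and 441, 99 and 193, 55 and 117, and 548 and 568, so preDP against DN3 has the fewest.

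DN3 is the stage gated as CD44 low and CD25 positive, at which the T-cell receptor beta locus is assembled. Compared with DN2, DN3 had higher levels of Ptcra, CD3 chain genes, Rag1 and Rag2 and lower levels of progenitor genes. Ptcra was at least 28.3-fold higher in DN3, Cd3d 24.5-fold, Cd3e 4.41-fold and the kinase gene Zap70 4.53-fold. Rag1, which encodes a subunit of the recombinase, was 15.0-fold higher and Rag2 2.08-fold. They were the 2 of 7 recombination genes at least 2-fold apart, and the list's median was 0.39 at percentile 98.5. Of 14 measured members of the T-cell receptor complex list, 6 were higher and 1 lower, with a median of 0.81 above every random list. T-lineage transcription factors had a median of 0.53 (0.85 without shared probe sets), with 5 of 13 higher and none lower. Lef1 was 5.31-fold higher and Id3 at least 6.33-fold. Gzma, a granule protease gene, was 8.30-fold higher, and Ldhb, Spats2 and Pld4 were 5.13-fold, 5.01-fold and 4.37-fold higher.

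Of 13 progenitor genes 7 were lower in DN3 and none higher, with a median of -1.34, below every random list, but -0.80 with the lower floor or the mean over probe sets and -0.76 with the higher floor. The transcription factor gene Lyl1 had a signal of 10202 in DN2 and was at least 78.2-fold lower in DN3. Nfe2 was 9.87-fold lower and Kit, the stem cell factor receptor, 5.30-fold. Cpa3, a mast cell protease gene, was 14.7-fold lower. Btk, Plcg2 and Lat2, signalling genes of B and myeloid cells, were 9.89-fold, 7.04-fold and 8.15-fold lower. Mpo was at least 11.4-fold lower, Cd74 8.19-fold and Napsa at least 24.3-fold. Dendritic cell markers had a median of -0.96 with 4 of 9 lower, but -0.14 with the higher floor, and mature single-positive markers one of -1.54 with 3 of 4 lower (-1.03 with the mean over probe sets). Cytokine receptor genes had a median of -0.67 with 6 of 15 lower. Natural killer markers had one of -1.06 with 2 of 4 lower and 1, Gzma, higher, but -0.05 with the higher floor. Myeloid markers had a median of -0.36 at percentile 3.65, and B-lineage markers 0.22 at percentile 89.9. Erythroid markers had one of -0.70 at percentile 1.80 with 2 of 4 lower, and the haemoglobin gene Hbb-b2 was at least 4.37-fold lower.

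Smaller shifts without large single genes were seen in further lists at this step. Ribosome biogenesis genes and Myc targets had a median of 0.40, above every random list, with no member 2-fold apart. G2 and mitosis genes had one of -0.37, below every random list, with Mki67 2.27-fold lower, and S phase genes one of -0.17 at percentile 1.39. Class I and interferon genes had a median of -0.33 at percentile 0.10 with no member 2-fold apart, and of -0.01 with plain probe sets alone. In total 99 genes were at least 2-fold higher and 193 lower, of 4894.

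The comparison of preDP with DN3 covers the passage past CD25 expression. It had the fewest genes 2-fold apart, 55 higher and 117 lower of 4825. Both CD8 genes were higher in preDP, and 5 of 6 measured Notch target genes were lower, among them Notch3 and the gate gene Il2ra. Cd8b1 was 19.6-fold higher, Cd8a at least 15.6-fold and Cd2 at least 5.18-fold. Trav9d-3, a variable segment of the T-cell receptor alpha locus, was 5.47-fold higher. Itgb2, Itm2a and Nr4a1 were 3.29-fold, 2.86-fold and 2.64-fold higher. The ubiquitin-conjugating enzyme gene Ube2s was 3.02-fold higher. G2 and mitosis genes had a median of 0.79 and S phase genes one of 0.57, both above every random list. Their members were mostly under 2-fold, with 3 of 24 and 2 of 24 at or over it, among them Bub1 at 2.25-fold and Rrm2 at 2.44-fold. The list of DP-stage genes had a median of 0.51, above every random list, with 2 of 11 higher and 2 lower.

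Myl10 was 14.8-fold lower in preDP, Hes1 8.00-fold, Dtx1 6.68-fold and Notch3 4.35-fold. Pld4 was at least 11.9-fold lower, Khdc1c at least 7.46-fold, Itgb4 at least 7.19-fold and Spib at least 4.86-fold. Ptcra was 3.13-fold lower, Cd3g 2.56-fold and Cd79b 4.04-fold. The gamma variable gene Trgv4 was 3.94-fold lower, and Il7r and Ccnd2 were 2.54-fold and 2.66-fold lower. Class I and interferon genes had a median of -0.57, below every random list, with H2-K1 2.08-fold lower. H2-Q1, a class I gene outside that list, was 4.14-fold higher. The probe sets of H2-K1 and H2-Q1 have the suffix _f_at and may also read related class I genes. Cytokine receptor genes had one of -0.41 at percentile 0.04, and progenitor genes one of -0.96 at percentile 0.05, with 2 of 5 members lower, but -0.30 under quantile normalisation. Mature single-positive markers had a median of 1.03, with Cd52 2.57-fold and Itgb7 2.04-fold higher and Il7r lower. That median was 0.48 with the higher floor and 0.51 with the mean over probe sets. Natural killer markers, with 3 members measured, had a median of 0.80 at percentile 99.5, but 0.07 with the floor at the 35th percentile. Myeloid, dendritic and B-lineage markers had medians of -0.30, 0.26 and -0.37, at percentiles 14.0, 91.5 and 1.15.

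By the count of genes 2-fold apart, DP against preDP was the largest of the consecutive comparisons, with 548 genes at least 2-fold higher and 568 lower than in preDP, of 4857. DP cells had higher coreceptor, T-cell receptor complex and cell cycle inhibitor genes. Lower in DP were the lists of the cell cycle, of ribosome biogenesis and Myc targets, and of glycolysis. DP alone came from total thymocytes. Cd4 was at least 39.1-fold higher and Cd8a 9.86-fold. Of 11 DP-stage genes 9 were higher and none lower, with a median of 2.55. That list holds Cd4, Cd8a and Cd8b1, genes of the CD4 and CD8 gate, so part of its result was fixed by the sort. Ets2 was 11.5-fold higher, Bcl2l1, an inhibitor of apoptosis, 5.91-fold and the chemokine receptor gene Ccr9 5.91-fold. Rag1 and Rag2 were 5.33-fold and 7.33-fold higher. Plxnd1 was at least 42.8-fold higher, Il4ra at least 22.4-fold and Mr1 at least 15.6-fold. The repressor gene Bcl6 was 13.3-fold higher, Trav9d-3 8.72-fold and the kinase gene Txk 11.5-fold. Of 17 T-cell receptor complex genes 10 were higher and none lower, with a median of 1.21, and Cd5 was 5.85-fold higher. Cell cycle inhibitor and quiescence genes had a median of 1.33, with 8 of 12 higher, among them Btg1 at 8.31-fold, Ccng2 at 5.33-fold and Cdkn2d at 3.28-fold. These 3 medians were above every random list.

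Of 24 S phase genes 21 were lower in DP, and of 24 G2 and mitosis genes 22, with medians of -1.50 and -1.51. Tk1 was 4.41-fold, Rrm1 4.16-fold and Cdc20 3.76-fold lower. Of 22 genes in the list of ribosome biogenesis and Myc targets 21 were lower, with a median of -2.03. Srm, the spermidine synthase gene, was 14.8-fold lower, Cad, an enzyme of pyrimidine synthesis, 8.95-fold and Mybbp1a 7.19-fold. Myc itself was at least 10.3-fold lower. All 3 medians were below every random list. The glycolysis list had a median of -0.81 at percentile 0.29, with 5 of 15 lower, and Tpi1 was 5.44-fold lower. The gamma-delta and innate-like T list had a median of -2.70 with all 3 measured members lower, among them Gzma at 23.4-fold. That median was -1.33 with the higher floor and -1.53 with the mean over probe sets. Outside this list, Trgv4 and Trgv1 were at least 28.2-fold and at least 23.1-fold lower. Plac8 was 30.4-fold lower. Without 75 listed cell cycle, ribosome biogenesis and Myc target genes, a choice made after seeing the values, 548 genes were higher and 504 lower.

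Further groups were higher in DP at smaller medians. T-lineage transcription factors had a median of 0.75 with 4 of 12 higher, and chemokine receptor and homing genes 0.73 with 5 of 11 higher. Immediate early and dissociation stress genes had one of 0.64 with 5 of 14 higher. Zfp36 was 7.67-fold higher. Apoptosis regulators had a median of 0.63 at percentile 98.3, with Fas at least 6.33-fold higher. Cytokine receptor genes had one of 0.75 at percentile 99.6, but -0.13 with the lower floor, so this list has no settled direction. Class I and interferon genes had a median of -0.04 at percentile 56.5. Within that list H2-K1 and H2-D1 were 2.67-fold and 2.21-fold lower and Igtp, an interferon-induced GTPase gene, was 5.18-fold higher. D-type cyclins had a median of -1.25 at percentile 2.75, with Ccnd3 2.70-fold higher and Cdk4 3.03-fold lower.

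**Figure D3:**
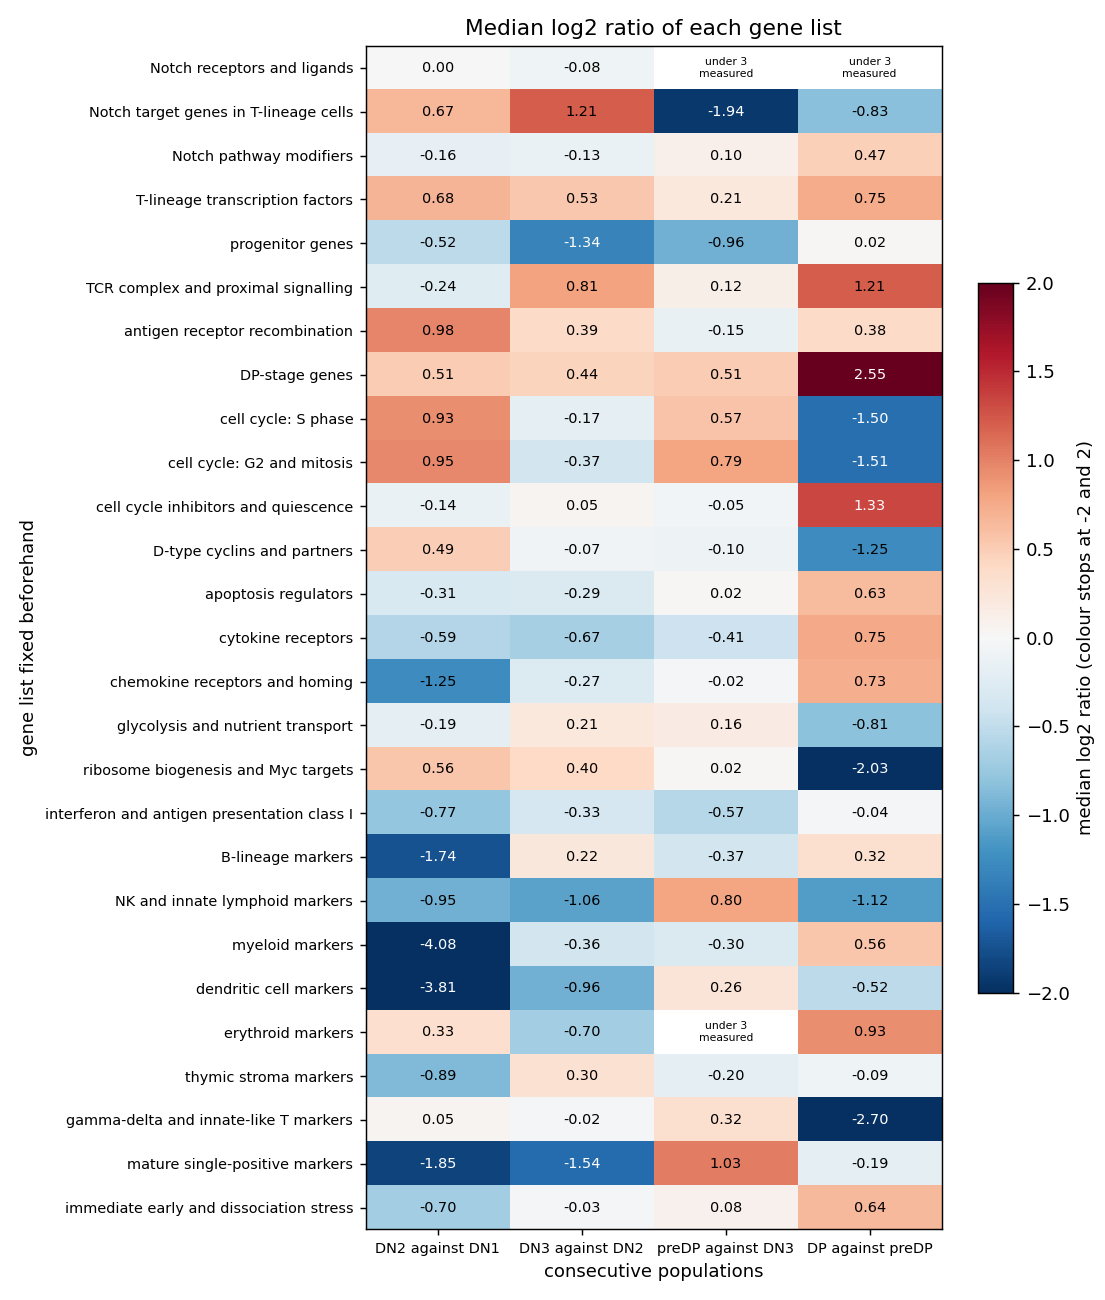
Median log2 ratio of the measured members of 27 gene lists (down) in the 4 consecutive comparisons (across), 1 array per population; red is higher and blue lower in the later population. Notch targets, which include Notch3 and the gate gene Il2ra, go from 1.21 in DN3 against DN2 to -1.94 in preDP against DN3. Without Notch3 the former median is 0.77. The list of ribosome biogenesis genes and Myc targets reaches -2.03 in DP. The T-cell receptor median in DN2 and the cytokine receptor median in DP turn sign under other settings.

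Across the whole span, 619 genes were at least 2-fold higher in DP than in DN1 and 723 lower, of 5211. T-cell receptor complex genes were higher for 14 of 17 members, with a median of 3.26, and all 11 DP-stage genes were higher, with a median of 3.27. The DP-stage list includes the genes of the CD4 and CD8 gate. Rag1 was at least 137-fold higher, Cd8b1 82.0-fold, Ets2 66.4-fold, Cd3g 19.4-fold and Ets1 17.1-fold. Progenitor genes were lower for 12 of 14 members, with a median of -3.12, and Lyl1 was at least 56.4-fold and Spi1 at least 25.9-fold lower. Myeloid and dendritic markers had medians of -5.30 and -4.90. Class I and interferon genes were lower for 15 of 19 members, with a median of -1.46, and H2-K1 was 16.2-fold lower. Notch1 was 2.23-fold lower in DP than in DN1, and Notch3 1.72-fold higher, though with the higher floor Notch3 was under it on both arrays. The higher floor gave medians of -1.93 for progenitor genes, -4.09 for myeloid and -4.00 for dendritic markers, and the mean over probe sets gave 2.32 for T-cell receptor complex genes. S phase and G2 and mitosis genes had medians of -0.36 each, at percentiles 0.26 and 0.39. Against DN2 in place of DN1, a comparison added after seeing the values, 491 genes were higher in DP and 633 lower.

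Of the 8251 genes, 2510 were at least 2-fold apart between their highest and lowest population. The highest value lay in DN1 for 634 of these genes, in DN2 for 290, in DN3 for 252, in preDP for 514 and in DP for 820. Without the DN1 array, an alternative added after seeing the values, 440 genes were highest in DN2. The DN1 count was 958 with the lower floor and 397 with the higher one. Genes at least 2-fold above both neighbouring populations numbered 29 in DN2, 20 in DN3 and 25 in preDP. Genes at least 2-fold below both numbered 19, 10 and 33. With values under the floor set to it, 46 genes at least 4-fold higher in DP than in DN1 were never lower in a later population, and 181 at least 4-fold lower were never higher. These include genes with a single difference and level values otherwise, such as Blnk, above the floor in DN1 alone and chosen after its values were seen.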

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

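All tests in this part were chosen only after the results they test were seen, and they replaced earlier tests that had also been run.

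Probe sets with no or several gene symbols were left out of the gene counts, and some held signal. Of 1589 such probe sets, 117 were at least 2-fold apart in DN2 against DN1, 38 in DN3 against DN2, 17 in preDP against DN3 and 119 in DP against preDP. A control probe set for Fas, also left out, had a signal of 1370.1 on the DP array and at most 68.8 on the others. The gene's own probe set gave 825 in DP and was under the floor elsewhere. These differences were not tested.

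Myeloid, dendritic and B-lineage genes were far higher in DN1 than in DN2, although DN1 was sorted as lineage negative. The lineage antibodies are not given in the sources used here. A scaling factor moves all genes of an array alike. The myeloid median log2 ratio was -4.08 and that of all genes 0.18, so myeloid genes differed relative to other genes. Every array had nearly the same trimmed mean, so the all-gene median was largely set by the scaling. It is therefore no test of the scaling itself or of total mRNA. Cells of these types in the DN1 sort may contribute, and so may expression in the progenitors themselves. Neither was tested, and both stay open. If DN1 held cells of other types, the share of all other transcripts on that array would change too. Folds of any gene against DN1, those of Notch1 and Notch3 among them, carry this limit.

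Cell cycle genes, and the list of ribosome biogenesis genes and Myc targets, were lower in DP than in preDP. The median log2 ratio of all genes was 0.0264, so these lists were lower relative to other genes. That median was largely set by the scaling of the arrays and cannot test it. The G2 and mitosis median of -1.51 could come from the change of stage or from the use of total in place of blast enriched thymocytes. These could not be separated, since no other array shared the source of DP.

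Notch target genes were higher in DN3 than in DN2. Fewer cells of other types in DN3 could raise all T-lineage genes together. The target median exceeded that of T-lineage transcription factors by 2.75 combined SDs of random lists. It exceeded that of T-cell receptor complex genes by 1.66. Ptcra is in both the target and the T-cell receptor list, so their medians are not independent, which the combined SD leaves out. The target median was 0.75 with the floor at the 35th percentile. The part of other cells therefore stays open. Without Notch3 itself the median of the other targets was 0.77, as it was without Dtx1 or without Ptcra. It was 1.66 without Hes1, without Il2ra or without Myc. Ptcra and Dtx1 were at least 2-fold higher, Hes1 and Myc under 2-fold and Il2ra lower, so the part of list membership stays open too. Whether Notch signalling itself differed was not measured.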

How the results depend on the processing

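With 1 array per population the number of arrays limits every result, and signals under the floor limit folds to lower bounds. No paired analysis was possible because each population had 1 array. Settings were compared one at a time, and except where stated the cause was not tested. Of the step counts 71 values stayed within 1.5 times, as did 42 peak counts, and 77 values of Notch1 and Notch3 and 494 list medians stayed within their tolerance. Of the other named genes 2552 values stayed, 516 moved and 1 turned sign. For list medians the tolerance was first 1 SD of random list medians, under which 410 of 550 stayed, 137 moved and 3 turned sign. It was widened to the central 95% range of random list medians after that run, in part because so many values were too many to print, and 53 then moved and 3 turned sign.

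Under quantile normalisation the T-cell receptor list in DN2 against DN1 turned sign, at 0.0142, and progenitor genes in preDP against DN3 had a median of -0.30. Scaling to an equal median left 144 genes higher in DN2 than in DN1.

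With the floor at the 35th percentile, more genes were counted by construction: 379 higher and 685 lower in DN2, 209 and 317 in DN3, and 151 and 256 in preDP, each against the stage before. Peaks numbered 958 in DN1 and 399 in DN3. In DN2 against DN1 the myeloid median was -3.38 and the dendritic -4.43. In DN3 against DN2 the medians were 0.75 for Notch targets, -0.80 for progenitor genes, 0.85 for DP-stage genes, -0.62 for dendritic markers and -1.04 for mature single-positive markers. The natural killer median was 0.0706 in preDP against DN3. Cytokine receptors turned sign in DP against preDP, at -0.13. In DP against DN1 the medians were -1.88 for class I and interferon genes, -1.91 for natural killer markers, -6.33 for myeloid markers and 0.34 for sort markers.

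With the floor at the 65th percentile, fewer were counted by construction: 262 lower in DN2 than in DN1, 51 higher and 101 lower in DN3 than in DN2, 30 and 63 in preDP against DN3, and 438 lower in DP than in DN1. Peaks numbered 397 in DN1, 192 in DN2 and 167 in DN3. The log2 ratio of Notch3 was 1.01 in DN2 against DN1 and 0 in DP against DN1, both values of the latter being under that floor. In DN2 against DN1 the medians were 1.09 for T-lineage transcription factors, -0.53 for chemokine receptors, -0.48 for class I and interferon genes and -3.21 for myeloid markers, and the T-cell receptor list turned sign at 0.45. In DN3 against DN2 they were 0.83 for T-lineage transcription factors, -0.76 for progenitor genes, 0.14 for DP-stage genes, -0.0471 for natural killer markers and -0.14 for dendritic markers. Mature single-positive markers had 0.48 in preDP against DN3. In DP against preDP cytokine receptors had 1.55, ribosome biogenesis genes and Myc targets -1.49 and the gamma-delta list -1.33. In DP against DN1 the medians were -1.93 for progenitor genes, 2.71 for the T-cell receptor list, -0.50 for cytokine receptors, -4.09 for myeloid and -4.00 for dendritic markers.

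With a constant added in place of a floor, 135 genes were higher in DN2 than in DN1, 63 higher and 128 lower in DN3 than in DN2, and 32 higher in preDP than in DN3. The log2 ratio of Notch3 in DN2 against DN1 was 1.496. Medians were -3.55 for myeloid and -3.36 for dendritic markers in DN2 against DN1, 0.75 for DP-stage genes and -0.61 for dendritic markers in DN3 against DN2, and -2.53 for progenitor genes in DP against DN1.

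With the mean over probe sets, B-lineage markers had a median of -1.01 and myeloid markers of -2.73 in DN2 against DN1. In DN3 against DN2 progenitor genes had -0.80 and mature single-positive markers -1.03, and the latter had 0.51 in preDP against DN3. The gamma-delta list had -1.53 in DP against preDP. In DP against DN1 the medians were 2.32 for the T-cell receptor list, 0.87 for cell cycle inhibitors, -0.94 for B-lineage and -3.56 for myeloid markers.

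Without shared probe sets the dendritic median was -4.42 in DN2 against DN1, and in DN3 against DN2 T-lineage transcription factors had 0.85 and DP-stage genes 0.14. With plain probe sets alone, a setting chosen after seeing the data, these 2 lists had 0.85 and 0.0179 and class I and interferon genes -0.0119. In DP against DN1 recombination genes had 2.30, and Numb turned sign, with a log2 ratio of -0.0308 in place of 1.45.

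At a 3-fold size the counts were smaller by construction: 37 higher and 241 lower in DN2, 28 and 61 in DN3, 10 and 32 in preDP and 207 and 179 in DP, each against the stage before, and 235 and 412 in DP against DN1. With the DN1 array left out, also chosen after seeing the data, 440 genes peaked in DN2, since genes highest in DN1 pass to another population. Without genes of other cell types 616 genes were higher in DP than in DN1 and 661 lower.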

Other observations

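No further tests were run for this part, and its genes were chosen after their values were seen. Several genes were at least 2-fold higher in 1 population than in both its neighbours. Cpa3, a mast cell protease gene, had a signal of 4451 in DN2, 926 in DN1 and 303 in DN3. Scin, an actin-severing protein gene, was 2329 in DN2, 480 in DN1 and 381 in DN3, and the growth factor gene Fgf3 was 873 in DN2 and 176 in DN1 and under the floor from DN3 on. In DN3 the integrin gene Itgb4 was 937 and Ctla4, an inhibitory receptor gene, 336, and Ctla4 was under the floor on the other arrays. In preDP the inhibitory receptor gene Pdcd1 was 797, the transcription factor gene E2f8 1818 and the helicase gene Hells 603. The transcription factor genes Xbp1 and Klf3 and the kinase gene Tec were lower in preDP than in both neighbours, at 599.9, 332 and 350.02.

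Gzma was above the floor on all arrays, at 261 in DN1, 349 in DN2, 2902 in DN3, 5036 in preDP and 215 in DP. The gamma variable gene Trgv4 was 1879 in DN1, 24961 in DN2, 14496 in DN3 and 3679.9 in preDP. It was under the floor in DP, as was Trgv1. The signals of the class I genes H2-K1 and H2-D1 were lower in each later population. Both probe sets have the suffix _f_at and may read related class I genes, so these may not be separate profiles. H2-K1 was 23674, 13841, 8092, 3897 and 1459 from DN1 to DP, and H2-D1 was 17276, 9985, 6388, 3326 and 1502. The samples were given as male, and the Y-linked gene Eif2s3y was above the floor on all arrays, at 404, 450.1, 204, 225 and 857. Xist, a marker of female cells, was 376 in DN3, 262 in preDP and 145 in DN2, and under the floor in DN1 and DP. Of the 4 sex marker genes listed and on the array, only Eif2s3y and Xist rose above the floor on any array. The check of the male label rests on them alone. The probe set of Eif2s3y has the suffix _f_at, so it may also read related genes.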
